A study of Mus musculus with 6 samples.

How the data were processed

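Gene expression was measured by RNA sequencing in 6 libraries of sorted interfollicular epidermis from the back skin of newborn mice, 3 labelled control and 3 labelled Ring1a and Ring1b double knockout. Per the labels' protocols, cells positive for EpCAM and Sca1 with high α6-integrin were sorted, 10 ng of RNA was amplified with the Nugen Ovation V2 kit, 100 ng of sonicated cDNA went into each library, and single reads of 100 nucleotides were sequenced. The deposited files hold counts per gene symbol that the authors made, 1 file per sample with 24453 symbols. Per the submitters' processing notes, the reads were handled with the mm10 genome, TopHat2 2.0.13, Cufflinks 2.2.1, HTSeq 0.6.1 and DESeq2 1.6.3. The notes used here do not assign the steps, the gene annotation or the strand of counting, so genes that overlap on opposite strands and near-identical paralogs may share reads. Values are whole numbers of uneven depth, as raw counts are. No symbol is a summary entry, and mitochondrially encoded genes are not in the files. The ribosomal RNA gene Rn45s took 5.64, 8.28 and 8.21% of the counts in control-labelled replicates 1 to 3 and 6.95, 10.4 and 8.55% in knockout-labelled replicates 1 to 3, and the 20 most counted genes took 17.2 to 21.7%. Of the symbols, 4569 had no count in any library.

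Groups were taken from the sample titles before the values were read, as were the tests, the gene lists, the rule for naming genes and the first set of alternatives, so these choices were made before the data were examined. The comparison of the knockout-labelled with the control-labelled libraries used edgeR 4.0.16 in R 4.3.3, with TMM normalization (factors 0.927 to 1.04), filterByExpr with a minimum count of 10 and a minimum total of 15, and a two-sided quasi-likelihood F test with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Fold changes used a prior count of 0.125. The biological coefficient of variation was 38.3%. Levels are CPM, counts scaled to a common size by the TMM library sizes, and ± gives the SD of 3 libraries for CPM and the model's SE for log2 fold changes. Where all 3 libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is a ratio of counts with a 95% interval for counting. The fitted log2 fold change of such genes is no bound.

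Lists of genes were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 30 lists with at least 5 tested members. Counts of called members were also taken after adjustment over the list alone. The lists covered Polycomb subunits, Hox genes, lineage transcription factors, germline genes, cell cycle and p53 genes, epidermal structure and differentiation, signalling pathways, stress responses and markers of other skin cell types. Genes are named by a rule: Ring1 and Rnf2, the 12 largest changes in each direction with a mean of at least 5 CPM in the higher group and no overlap between groups, up to 4 called members of each list with the smallest p (without any, the member with the highest mean), and any Polycomb subunit. Predicted and unnamed genes were left out of the 12. Some genes that the rule names are not reported here. Other genes named were chosen after their values were seen. Chromosome positions are from GENCODE M21 on GRCm38, in which 23753 symbols matched 1 gene.

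The alternatives set beforehand were size factors of DESeq2 1.42.0 or library size alone for scaling, no count filter or a filter of 50 counts in 3 samples, a replicate block, DESeq2 and limma-voom as tools, a 2-fold minimum and leaving out each library. Those added after the data were seen were the Xist level as a covariate, replicates 1 and 2 or replicates 2 and 3 of each group alone, the split on the second principal component as a term, removal of the 20 most counted genes, and an offset for GC content and transcript length, which were known for 97.8% of tested genes. The pipeline was tested on simulated counts of the same 14890 genes and 3 against 3 libraries. It recovered 19.4% of 67 genes changed 2-fold, 67.2% of 64 changed 4-fold and 93.8% of 64 changed 16-fold, so most 2-fold changes were missed in the simulation. It made 8 false calls beside 200 changed genes and 0 calls with no gene changed. The comparison itself called 1512 genes. Fewer changed genes make the adjusted p stricter, so the shares recovered in the simulation are not those of the comparison. The libraries are not copies of each other, since the smallest chi-square per degree of freedom of a pair was 28.6. Figures used matplotlib 3.10.9 in Python 3.11.15.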

Results

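RNA sequencing measured gene expression in epidermal cells sorted from the back skin of newborn mice (postnatal day 0). The sort kept cells positive for EpCAM and Sca1 with high α6-integrin, surface proteins that together select interfollicular epidermis and enrich for its progenitors. 3 libraries were labelled control and 3 were labelled as double knockouts of Ring1a and Ring1b. Ring1a (gene Ring1) and Ring1b (gene Rnf2) are the catalytic E3 ubiquitin ligases of Polycomb repressive complex 1 (PRC1), which ubiquitinates histone H2A and keeps developmental genes silent. The comparison addresses what PRC1 does in the developing skin epithelium, the subject that the title of the series names. C1, C2 and C3 stand for control-labelled replicates 1, 2 and 3, and K1, K2 and K3 for knockout-labelled replicates 1, 2 and 3. Summed over all gene symbols, C1, C2 and C3 held 26599231, 22699108 and 29193535 counts, and K1, K2 and K3 held 31187270, 18951665 and 29651209. A library with 0 counts of a gene could hold up to 3, which is 0.0962 to 0.158 CPM (counts scaled to a common library size) at these depths. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. The sex-linked transcript Xist ranged from 6.91 to 1757 CPM in the control-labelled and from 4.48 to 6133 CPM in the knockout-labelled libraries. These values argue against 3 technical repeats of 1 source in either group. The first principal component of log CPM, with 56.7% of the variance, separated the 2 labelled groups. The second, with 18.5%, set C1 and K1 (55.3 and 62.7) apart from the other libraries (-38.8 to -15.2). Correlations of log CPM across genes were 0.930 to 0.966 within groups and 0.841 to 0.905 between them.

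The targeted genes did not separate the libraries by label. Ring1 (chromosome 17, 34020792 to 34024680, minus strand, GRCm38) had 30.9, 17.1 and 3.90 CPM in C1, C2 and C3, and 1.66, 5.20 and 14.2 CPM in K1, K2 and K3. In the replicate 3 libraries the order was thus against the labels, with K3 above C3, and the libraries are called by their labels throughout. Every direction given here is that of the knockout-labelled against the control-labelled libraries. The Ring1 log2 fold change of -1.29 ± 0.83 (SE, n = 3 libraries per group) did not pass (edgeR adjusted p = 0.389), nor did the -2.82 found with replicates 1 and 2 alone, a setting chosen after the data were seen (edgeR adjusted p = 0.0658). Rnf2 (chromosome 1, 151458004 to 151500955, minus strand) had 43.2, 63.2 and 47.5 CPM in C1, C2 and C3 and 55.4, 64.1 and 59.0 CPM in K1, K2 and K3, with a log2 fold change of 0.21 ± 0.20 (SE; edgeR adjusted p = 0.575). The deleted part of either gene is not given in the sources used here. Counts per gene include reads outside a deleted part, so the Rnf2 counts check no label. Sex-linked transcripts did not follow the labels either. Xist, which is transcribed from the inactive X chromosome, had 10.5, 6.91 and 1757 CPM in C1, C2 and C3 and 6133, 4736 and 4.48 CPM in K1, K2 and K3. The Y-linked gene Ddx3y had 91.2, 102 and 59.7 CPM in C1, C2 and C3 and 0.0346, 0.206 and 76.2 CPM in K1, K2 and K3, so C3 held both transcripts. The libraries with high Xist (C3, K1 and K2) were also those with the lowest Ring1. The Ring1 split therefore cannot be told apart from the Xist split. No group difference in the 5 sex-linked genes passed, and without K3 4 of them were lower.

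Among the other Polycomb genes, few moved. Of 25 PRC1 subunits 3 were called, the same 3 under adjustment over all genes and adjusted over the list alone. Pcgf2, a RING-finger partner of the ligases, fell (114 ± 22.6 against 61.7 ± 3.04 CPM, mean ± SD; edgeR adjusted p = 0.0217). The corepressors Bcor and Bcorl1, scaffolds of a variant PRC1, rose by 0.81 and 1.03 on the log2 scale. With an offset for GC content and transcript length 2 members were lower and none higher (Bcor 0.42 and Bcorl1 0.54 on the log2 scale, edgeR adjusted p = 0.205 and 0.219), and the list's median log2 fold change turned from 0.09 to -0.11. The list test did not pass (camera adjusted p = 0.538). Of the 11 subunits of Polycomb repressive complex 2 (PRC2) edgeR called 0, with 3 lower at an unadjusted p under 0.05 and 2 called lower by DESeq2 and 0 by limma-voom, and 2 lower with the offset. Adjusted over the list alone, Ezh2, its histone H3 methyltransferase, and Phf19 were lower (126 ± 13.8 to 72.9 ± 20.3 and 19.1 ± 3.68 to 9.57 ± 2.09 CPM), and both missed the threshold over all genes (edgeR adjusted p = 0.0721 and 0.0578). Calls were lost, with edgeR adjusted p in parentheses, for Pcgf2 without C3, K2 or K3 (0.0617 to 0.0828), Bcor without C1, C2, C3 or K2 (0.0526 to 0.106) and Bcorl1 without any 1 library (0.0526 to 0.0961). In all, 2 PRC1 subunits were called without C1 (Pcgf2, and Phc1 newly at 0.0380) or K1, 1 without C2 or K3 and 0 without C3 or K2.

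**Figure D1:**
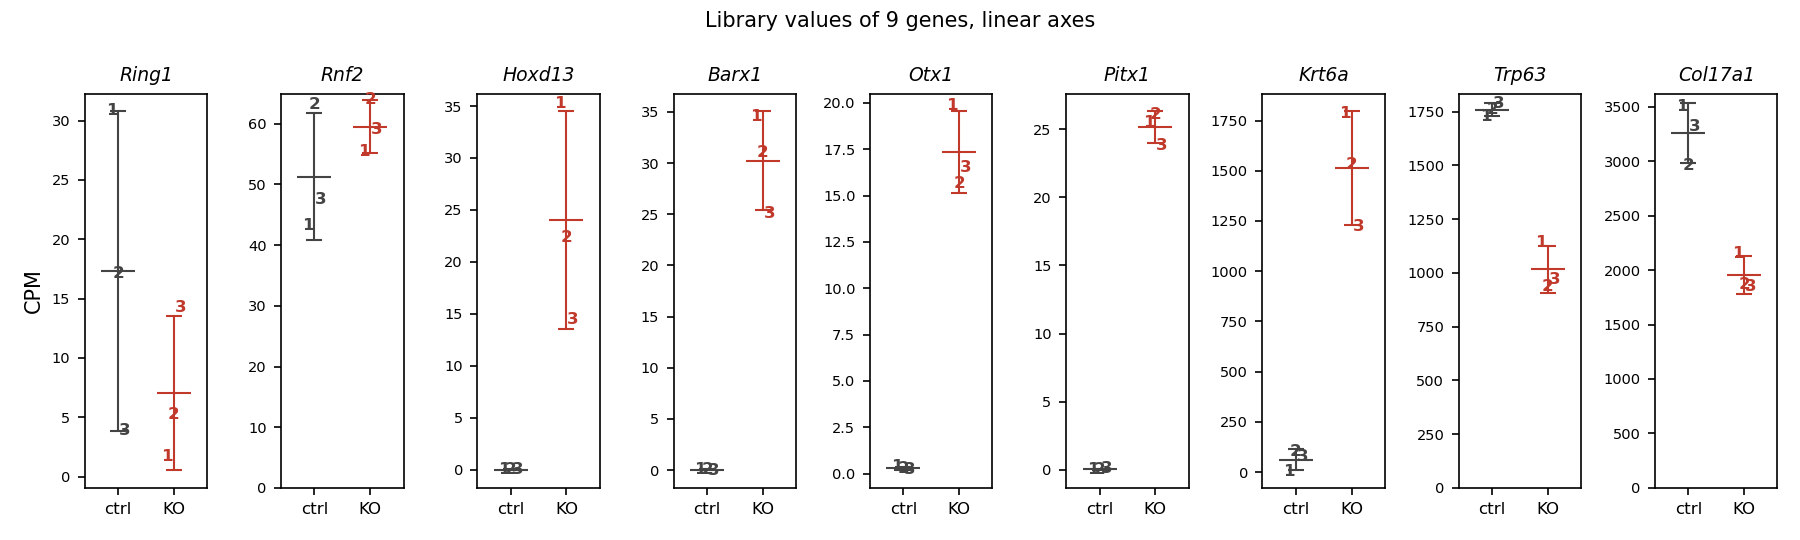
CPM of 9 genes in each library on linear axes, with replicate numbers as the points and the mean ± SD of 3 libraries as bars, for libraries labelled control (ctrl) and double knockout (KO). Ring1 was lower in C3 (3.90 CPM) than in K3 (14.2 CPM), while the highest control-labelled library stayed below the lowest knockout-labelled library for Hoxd13, Barx1, Otx1, Pitx1 and Krt6a, and the reverse held for Trp63 and Col17a1.

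The knockout-labelled epidermis expressed many genes that the control-labelled epidermis expressed little or not at all. Of 14890 genes tested, 1512 (10.2%) changed, and 1068 of them, 70.6%, were higher. 371 of the higher genes (34.7%) had a mean under 1 CPM in the control-labelled libraries, and 53 had no count there. Their median control-labelled level was 2.94 CPM, against 17.0 CPM for all tested genes and 55.8 CPM for the 444 lower genes. A gene can be called lower only if it was counted in the control-labelled libraries, so part of this difference comes with the calls. Of the lower genes, 54 had a mean under 1 CPM in the knockout-labelled libraries. Among changes of 4-fold or more, 691 were higher and 110 lower. With an offset for GC content and transcript length, chosen after the data were seen, which moved the median log2 fold change of all tested genes by -0.13, 1833 genes were called and 49.3% of them were higher, against 70.6% without it. In 4826 tested genes (32.4%) the CPM of the 2 groups did not overlap, against the 10% that chance gives for 3 against 3.

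The genes with the largest increases are known from other organs. Dmrt3, a doublesex-related transcription factor of spinal cord and gonad (chromosome 19, 25610301 to 25623921), had 0 counts in C1, C2 and C3 and 11.7 ± 1.85 CPM in K1, K2 and K3, at least 314-fold higher against a floor of 3 counts over the group. Its neighbour Dmrt1, of the same family (chromosome 19, 25505618 to 25604329), was at least 151-fold higher. Also without a count in the control-labelled libraries were Nfasc, an adhesion molecule of the axon initial segment (at least 203-fold higher), C1ql1, a secreted C1q-like protein of neurons (at least 193-fold), and Nkx6-1, a homeobox factor of neural tube and pancreas (at least 135-fold). Hoxd13, a factor of digits and genitalia (chromosome 2, 74668310 to 74671599), had 1 count in the control-labelled libraries and 24.0 ± 10.5 CPM in the knockout-labelled ones, a ratio of 1887 (95% interval 338 to 74586). Barx1, a factor of stomach and facial mesenchyme (chromosome 13, 48662998 to 48666507), reached 30.2 ± 4.82 CPM from 3 counts, a ratio of 788 (269 to 3823). Wt1, a factor of kidney and gonad, rose from 1 count with a ratio of 903, and leaned on K1 (22.8, 4.94 and 4.91 CPM in K1, K2 and K3). Slc7a10, an amino acid transporter, Sox1 and Hoxa10 also rose from 1 count each, with ratios of 895, 779.8 and 774. These intervals and floors cover counting error only, since the labels name no molecular identifiers. The largest decreases included differentiation and hair genes. Krt25, a keratin of the hair follicle's inner root sheath, fell from 7.73 ± 5.50 CPM to 0 counts, at least 193-fold lower. Kcnj16, a potassium channel, went from 12.4 ± 6.69 CPM to 1 count (ratio 943, 169 to 37278). Gadl1, a decarboxylase, had a log2 fold change of -6.78 ± 0.83 (SE), Dio2, the deiodinase that activates thyroid hormone, of -6.17 ± 0.65, Tgm5, an epidermal transglutaminase, of -6.05 ± 0.92, and Pi15, a secreted protein, of -5.95 ± 0.45. Pglyrp4, an antibacterial peptidoglycan-binding protein of skin, fell from 15.9 ± 1.02 to 0.399 ± 0.299 CPM. Cyp2f2, Txlnb, Pik3c2g, Klhl38 and Lrrc31 completed the 12 largest decreases, at log2 fold changes of -6.10, -5.94, -4.77, -4.45 and -4.43. The edgeR adjusted p of the genes named in this paragraph was 2.67e-04 to 0.0253.

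The count of changed genes depended on single libraries. It was 811 without C3, 821 without K2 and 995 without K3, and the count of lower genes was 283 without C1, 269 without C2, 181 without C3, 174 without K2 and 244 without K3. In settings chosen after the data were seen, it was 439 with replicates 1 and 2 alone, 2694 with replicates 2 and 3 alone and 550 with the Xist level as a covariate. Of the genes named above with the largest changes, calls were lost (edgeR adjusted p) for Klhl38 without C1, C2, K2 or K3 (0.0600 to 0.0802) and Lrrc31 without C1, C3 or K2 (0.0523 to 0.0839).

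**Figure D2:**
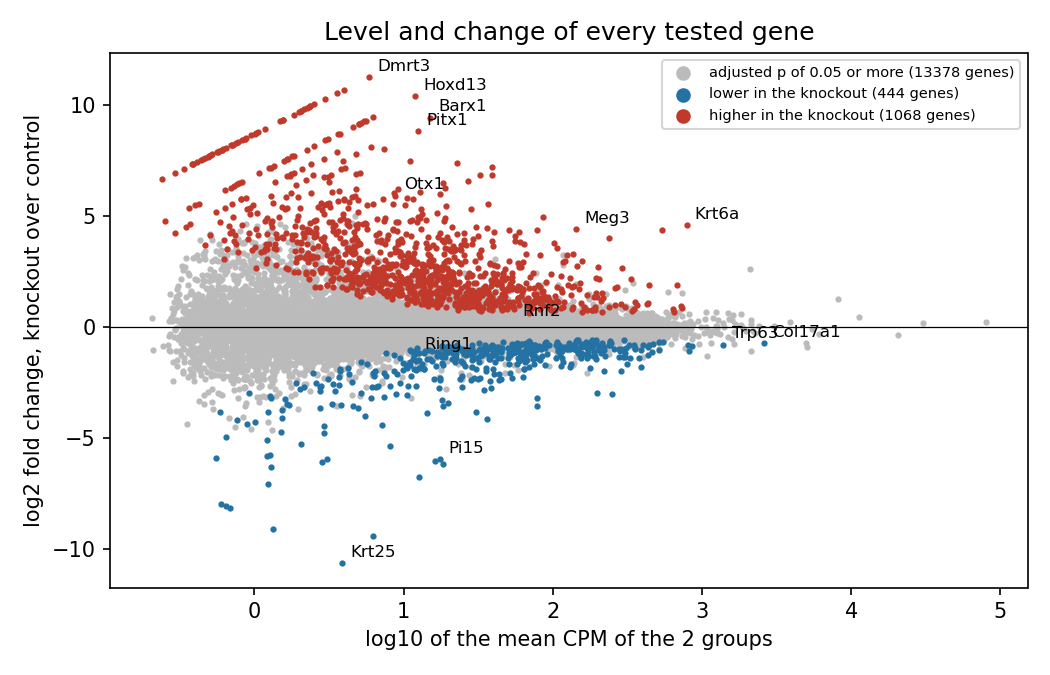
Each point is 1 of 14890 tested genes, placed by the log10 of its mean CPM over the 2 groups (horizontal) and its log2 fold change, knockout-labelled over control-labelled (vertical), with 1068 genes called higher in red, 444 called lower in blue and the others in grey. Higher genes reach large fold changes at low levels, where the fitted values of genes without control-labelled counts are no bounds, and lower genes lie mostly at higher levels.

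Many transcription factors that specify other lineages rose. Of 28 tested neural lineage factors (63 listed), 19 rose and the other 9 did not pass, and 21 were higher adjusted over the list alone. Otx1, a forebrain factor, rose from 0.281 ± 0.0865 to 17.3 ± 2.21 CPM, Zic1, a cerebellar factor, from 0.531 ± 0.562 to 34.3 ± 6.81 CPM, and Pax3, a factor of neural crest and dorsal neural tube, from 0.513 ± 0.340 to 14.3 ± 1.69 CPM. Of 40 tested mesoderm and endoderm factors (64 listed), 25 rose and the other 15 did not pass, and 29 were higher and 1 lower adjusted over the list alone. Pitx1, the hindlimb factor, rose from 0.0488 ± 0.0515 to 25.1 ± 1.17 CPM, a log2 fold change of 8.83 ± 0.57 (SE; edgeR adjusted p = 3.03e-04). Tbx15, a factor of limb and dorsal dermis, rose from 1.91 ± 0.302 to 19.5 ± 4.30 CPM, and Barx1 and Wt1 were members of this list, as Sox1 was of the neural list. The median log2 fold change was 5.73 for the neural list, 4.60 with its 6 members that lacked control-labelled counts set at their bounds, and 3.96 for the mesoderm and endoderm list. Both lists passed against the other genes (camera adjusted p = 2.84e-24 and 4.33e-26). They were also the 2 of 30 tested lists that passed when the correlation between genes was estimated (camera adjusted p = 0.00447 for each). The remaining 35 neural and 24 mesoderm and endoderm factors were not tested. A factor silent in the control-labelled libraries met the count filter only if it was counted in the knockout-labelled ones. The shares that rose, the medians and these p-values therefore hold for the tested members only. Both lists also passed without a count filter, but a gene still had to be counted in some library, so that setting does not remove the selection. No call of a factor named in this paragraph was lost when any 1 library was left out.

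Hox genes moved in opposite directions along their clusters. Of 36 tested Hox genes 10 rose and 5 fell, and 12 were higher and 9 lower adjusted over the list alone. The higher genes were mainly of the posterior paralog groups. Hoxc10 rose from 0.753 ± 0.602 to 26.0 ± 3.72 CPM (log2 fold change 5.12 ± 0.62, SE; edgeR adjusted p = 0.00189), and Hoxc12 from 3 counts to 12.1 ± 2.11 CPM (ratio 319, 109 to 1551). Hoxd13 and Hoxa10 belong here too. The lower genes, named after their values were seen, included Hoxa2, Hoxa3, Hoxa7 and Hoxc4, with log2 fold changes of -2.72, -1.90, -1.42 and -2.21. Hoxa3 and Hoxc4 varied widely among the control-labelled libraries (18.6 ± 12.4 and 40.6 ± 36.1 CPM, mean ± SD), so the size of their changes is uncertain. In paralog groups 1 to 8, 1 of 22 tested genes rose and 5 fell, and in groups 9 to 13, 9 of 14 rose. The exception was Hoxd1, also named after its value was seen, at least 16.6-fold higher from 0 control-labelled counts, at 0.672 CPM. As a list the Hox genes did not pass (camera adjusted p = 0.0594), with a median log2 fold change of -0.13 against a positive mean and an upward test. The list passed without C1 (0.0357), C2 (0.0364) or K1 (0.0222), without a count filter (0.0206), with the Xist covariate (0.00150), with replicates 2 and 3 alone (0.0175) and with the GC and length offset (0.0438, camera adjusted p). The strand of counting is not given in the sources used here, so reads of overlapping or antisense transcripts within the clusters cannot be told apart. Calls were lost (edgeR adjusted p) for Hoxa3 without C1, C3, K1, K2 or K3 (0.0679 to 0.118), Hoxc4 without C1, C3, K1, K2 or K3 (0.0578 to 0.134) and Hoxd1 without any 1 library (0.0565 to 0.108), and the 5 lower genes became 3 without C1, C3, K1, K2 or K3.

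The main keratins of the epidermis did not pass, while some genes of basal identity and adhesion changed. Krt5 and Krt14, the keratins of basal cells, had log2 fold changes of -0.37 and -0.32, and Krt1 and Krt10, those of suprabasal cells, -0.54 and -0.19 (edgeR adjusted p = 0.350 to 0.890). These 4 were named after their values were seen. Of 15 basal identity genes 2 rose and 3 fell, under both adjustments. Trp63, the master regulator of stratified epithelium, fell from 1759.8 ± 30.4 to 1016 ± 108 CPM, and the Notch ligand Dll1 fell by 1.04 on the log2 scale. Zfp750, a driver of terminal differentiation, rose by 0.93, and Tfap2c by 1.11. Of 32 genes of hemidesmosome, integrins and basement membrane 7 fell and 2 rose (9 and 3 adjusted over the list alone). Lama3, a chain of laminin-332, fell from 1107 ± 79.9 to 602 ± 62.2 CPM, Frem2 fell by 1.17 and the collagen receptor Itga2 by 0.89 on the log2 scale, and the adaptor Fermt2 rose by 1.55. Neither list passed (camera adjusted p = 0.131 and 0.176), and the hemidesmosome list had a median log2 fold change of 0.06, a mean of -0.04 and a downward test. With the GC and length offset its median was -0.57, 13 members fell and the list passed (camera adjusted p = 1.52e-04), as it did without K1 (0.0174), with the Xist covariate (0.0338) and with replicates 2 and 3 alone (0.0208), and the basal list passed with the offset (0.0279), which called 5 of its members lower, and by fry (fry adjusted p = 0.0182). Without 1 library, calls ended (edgeR adjusted p) for Trp63 without C2, C3, K2 or K3 (0.0683 to 0.0880), Dll1 without C2 or K2 (0.0802 to 0.0851), Zfp750 without C3 (0.0599), Tfap2c without C3, K2 or K3 (0.0606 to 0.0682), Lama3 without K2 (0.0676), Frem2 without K2 (0.0689), Itga2 without C2, C3 or K2 (0.0732 to 0.0894) and Fermt2 without C2 or C3 (0.0571 to 0.0639). The 7 lower genes of hemidesmosome, integrins and basement membrane became 2 without C2 or C3, 0 without K2 and 4 without K3, and the 2 higher ones 0 without C2 or C3 and 1 without K1 or K3. The 3 lower basal genes became 0 without C2 or K2, 1 without C3 and 5 without K1, and the 2 higher ones 0 without C3 and 1 without K2 or K3.

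Some genes of cell junctions, cytoskeleton, differentiation and wounding rose, while most members of each list did not pass. Of 24 junction genes 5 rose and the other 19 did not pass (7 higher adjusted over the list alone). The plakophilin Pkp2 rose from 1.62 ± 0.601 to 27.4 ± 8.34 CPM, the desmosomal cadherin Dsc2 by 1.64 and the adhesion receptors Nectin1 and Nectin4 by 1.17 and 1.80 on the log2 scale. Of 29 actin cytoskeleton genes 5 rose and the other 24 did not pass (6 higher and 1 lower adjusted over the list alone). They included the myosins Myl9 (log2 fold change 4.06 ± 0.47, SE) and Myh10 (2.44 ± 0.30) and the tropomyosins Tpm1 and Tpm2 (1.89 and 2.18). Of 34 suprabasal differentiation genes 10 rose and 1 fell (12 and 1 adjusted over the list alone). Abca12, the lipid transporter of the skin barrier, rose by 1.75 ± 0.22 (SE), Klk7, a protease of shedding corneocytes, by 2.27 and Grhl3, a factor of barrier formation, by 1.89 on the log2 scale. Tgm3, a transglutaminase, fell from 30.2 ± 6.69 to 4.48 ± 1.53 CPM. Of 17 wound and stress genes 5 rose and the other 12 did not pass (10 higher adjusted over the list alone). Krt6a, a keratin of wounded and hyperproliferative epidermis, rose from 61.7 ± 51.2 to 1513 ± 282 CPM, and the cornified envelope precursors Sprr1a and Sprr1b by 4.37 ± 0.60 and 4.10 ± 0.81 on the log2 scale (SE). Krt6a shares sequence with Krt6b, and Sprr genes with each other, so the split of reads among them is uncertain. All 4 lists passed upward (camera adjusted p = 0.00744, 0.0111, 0.00405 and 2.70e-04 in the order given). None did with an estimated correlation (camera adjusted p = 0.408, 0.599, 0.599 and 0.293). The junction list also lost its call with the GC and length offset (0.0541), the actin list with the offset (0.0611), with replicates 2 and 3 alone (0.275), with the Xist covariate (0.294) and without K1 (0.163), and the suprabasal list without C1 (0.0548) or K2 (0.0535, camera adjusted p). With fry the actin and suprabasal lists did not pass either (fry adjusted p = 0.176 and 0.212). Leaving out 1 library ended the calls (edgeR adjusted p) of Nectin1 without K2 or K3 (0.0503 to 0.0508), also with the GC and length offset (log2 fold change 0.44, 0.306), Nectin4 without C3, K2 or K3 (0.0765 to 0.0767), Krt6a without C3 (0.0523) and Sprr1b without C3 (0.0504). Of the counts, the 5 junction genes became 3 without C3 and 2 without K2 or K3, the 10 suprabasal genes 6 without C3 and 5 without K2, and the 5 wound genes 3 without C2, K1 or K2 and 1 without C3.

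Some inhibitors of the cell cycle and p53 targets rose. Of 7 cyclin-dependent kinase inhibitors 3 rose and the other 4 did not pass (4 higher and 2 lower adjusted over the list alone). Cdkn2a, the locus of p16 and p19Arf and a known Polycomb target, had 0 counts in C1, C2 and C3 and 1.56, 1.03 and 1.69 CPM in K1, K2 and K3, at least 38.8-fold higher. Cdkn1c rose from 18.9 ± 3.73 to 71.6 ± 4.41 CPM and Cdkn1a, the p21 gene and a p53 target, from 253 ± 7.35 to 445 ± 27.9 CPM. The list did not pass (camera adjusted p = 0.0594), but did without K1 (0.0429), without a count filter (0.0368), with the Xist covariate (0.0332) and by fry (fry adjusted p = 0.00686). Of 18 p53 target genes 8 rose and the other 10 did not pass (10 higher adjusted over the list alone). Zmat3, an RNA-binding p53 target, rose from 119 ± 13.4 to 421 ± 94.2 CPM, Ccng1 by 1.36 and the apoptosis gene Pmaip1 by 1.14 on the log2 scale. The list passed upward (camera adjusted p = 2.76e-05; adjusted p = 0.165 with an estimated correlation). Of 32 proliferation genes 1 fell and the other 31 did not pass by edgeR (15 lower at an unadjusted p under 0.05, 6 called lower by DESeq2 and 1 by limma-voom, and 0 adjusted over the list alone), and 3 fell with library size alone or with the GC and length offset. Mcm4, a subunit of the replicative helicase, fell by 0.87 on the log2 scale. The list passed downward with a median log2 fold change of -0.61 (camera adjusted p = 4.53e-06; adjusted p = 0.438 with an estimated correlation; fry adjusted p = 0.0559). Calls were lost (edgeR adjusted p) for Cdkn1a without C2 or C3 (0.0501 to 0.0661) and Mcm4 without C1, C2, C3 or K3 (0.0661 to 0.114). The 8 higher p53 targets became 4 without C3 and 5 without K2 or K3, and the 1 lower proliferation gene 0 without C1, C3 or K3, 2 without C2 and 6 without K1.

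Signalling genes changed in both directions. Of 12 hedgehog pathway genes 3 fell and the other 9 did not pass (4 lower adjusted over the list alone), and 5 fell with the GC and length offset, which moved the median log2 fold change from -0.67 to -1.31. The hedgehog co-receptors Cdon and Gas1 fell from 399 ± 95.4 to 156 ± 34.7 CPM and from 225 ± 40.1 to 116 ± 14.5 CPM, and the effector Gli2 fell by 1.01 on the log2 scale. The list passed downward (camera adjusted p = 0.00441; adjusted p = 0.545 with an estimated correlation; fry adjusted p = 0.154). Of 31 Wnt and BMP genes 8 rose and 3 fell (10 and 4 adjusted over the list alone). The secreted Wnt modulators Sfrp2, Sfrp1 and Dkk3 rose by 3.94 ± 0.24, 1.70 ± 0.19 and 1.29 ± 0.21 (SE), and the ligand Wnt5a from 0.838 ± 0.218 to 15.0 ± 3.91 CPM. The 3 lower genes, of which Wnt4 and Wnt16 were named after their values were seen, were Lef1 (-1.12), Wnt4 (-1.26) and Wnt16 (-1.09). The list passed upward with a median log2 fold change of 0.25 (camera adjusted p = 0.0279; adjusted p = 0.459 with an estimated correlation). It did not pass without C2 (0.113) or K3 (0.0949), with replicates 1 and 2 alone (0.150), with a stricter count filter (0.0568) or with the GC and length offset (0.157), which turned its median to -0.04 and called 6 lower. Of 23 interferon response genes edgeR called 0, with 5 lower at an unadjusted p under 0.05, 3 called lower by DESeq2, 0 by limma-voom and 1 lower with library size alone. That list passed downward (camera adjusted p = 0.0140; adjusted p = 0.591 with an estimated correlation; fry adjusted p = 0.212), but not without C3 (0.142) or K1 (0.0558), with a stricter filter (0.110), with replicates 1 and 2 alone (0.135) or with the offset (0.0606). Of 19 immediate-early and dissociation genes edgeR called 0 (5 lower at an unadjusted p under 0.05, 1 lower by DESeq2, 0 by limma-voom, 2 lower with the offset), and Egr1 had 2083 ± 1423 and 1830.3 ± 1105 CPM. That list did not pass (camera adjusted p = 0.227), but did without C3 (0.0349) or K1 (0.0388). Of 10 tested germline genes Mei1, a meiotic gene, rose from 0 counts to 1.29 ± 0.363 CPM, at least 35.2-fold (2 higher adjusted over the list alone; 2 higher with the offset; camera adjusted p = 0.188). Without 1 library, calls ended (edgeR adjusted p) for Gas1 without C3, K2 or K3 (0.0619 to 0.0780), Gli2 without C1, C3, K2 or K3 (0.0635 to 0.134), Lef1 without K2 (0.0698) and Wnt16 without C2, C3 or K3 (0.0512 to 0.0706). The 3 lower hedgehog genes became 5 without K1 and 1 without C3, K2 or K3. The 1 germline gene became 2 without C1 or C2, and 1 gene was called lower of the interferon list without C1 or C2 and of the immediate-early list without C3 or K1.

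Some markers of simple epithelium and Merkel cells rose, and edgeR called no marker of immune cells, melanocytes, muscle or nerve sheath. Of 8 simple epithelium genes 2 rose and the other 6 did not pass (4 higher adjusted over the list alone), namely the keratin Krt18 (0.851 ± 0.476 to 37.6 ± 26.1 CPM) and the claudin Cldn6 (1.53 ± 0.627 to 72.3 ± 24.8 CPM). Of 9 tested markers (16 listed) of Merkel cells, the touch-sensing cells of the epidermis, 4 rose and the other 5 did not pass (6 higher adjusted over the list alone). They were Krt18, the factors Sox2 and Isl1, both without control-labelled counts and at least 80.7-fold and 85.0-fold higher, and the mechanosensitive channel Piezo2 (1.95 ± 0.31, SE). Both lists passed upward (camera adjusted p = 1.71e-06 and 5.22e-06, and 0.110 and 0.0692 with an estimated correlation). A marker silent in the control-labelled libraries was tested only if it was counted in the knockout-labelled ones. These p-values therefore hold for the tested members only. Of 7 sebaceous gland genes Krt79, also a keratin of the hair canal, rose from 27.3 ± 14.9 to 448 ± 55.8 CPM. Hair markers went both ways. Of 10 hair shaft and inner root sheath genes 1 rose (Krt85) and 3 fell (Krt25, Krt27 and Krt71), or 3 and 3 adjusted over the list alone. Of 19 hair germ genes 1 rose (Tbx1, 0 with the GC and length offset) and 2 fell, or 3 and 2 adjusted over the list alone, the lower ones being Lef1 and Sostdc1, a BMP and Wnt antagonist (141 ± 60.4 to 15.0 ± 9.96 CPM). Of 17 dermal fibroblast genes 4 rose and 1 fell, under both adjustments. Fbn1, Fstl1, Col6a2 and Col5a1, genes of the extracellular matrix, rose by 2.08, 1.79, 1.55 and 1.46 on the log2 scale, while Postn, named after its value was seen, fell by 1.10. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1, named after their values were seen, had log2 fold changes of 0.23, -0.09 and 0.34, none of which passed. The sebaceous, hair shaft, hair germ and fibroblast lists did not pass (camera adjusted p = 0.142, 0.0983, 0.901 and 0.0925), and the hair germ list had a median log2 fold change of 0.21, -0.24 with the GC and length offset, and a downward test. They passed (camera adjusted p) without C1 for sebaceous gland (0.0459) and fibroblast (0.0295), without C3 for fibroblast (0.0495) and hair shaft (0.00306), and without K1 (0.0388) or K2 (0.0343) for hair shaft. With fry the sebaceous list passed (fry adjusted p = 0.0270). With replicates 2 and 3 alone the sebaceous (0.0456) and fibroblast (0.0169) lists passed, with the Xist covariate the fibroblast list (0.0228), and with replicates 1 and 2 alone (0.0149) or without a count filter (0.0206) the hair shaft list (camera adjusted p). Leaving out 1 library ended the calls (edgeR adjusted p) of Krt27 without C2, K1, K2 or K3 (0.0547 to 0.116), Krt71 without C2, K1 or K3 (0.0526 to 0.0997), Krt85 without C1, C3, K1, K2 or K3 (0.0573 to 0.151), Tbx1 without C2, K1, K2 or K3 (0.0946 to 0.112), Col6a2 without C3 (0.0523), Postn without C3 (0.0504) and Lef1 without K2 (0.0698). Tbx1 and Krt85 were also lost when scaled by library size alone (0.0506 and 0.0511), Tbx1 with the strict filter (0.0519) and the offset (log2 fold change 2.23), and Krt27 by limma-voom (0.0613). The 1 higher hair germ gene became 4 without C1 and 0 without C2, K1, K2 or K3, the 1 higher hair shaft gene 0 without C3, K1, K2 or K3, and the 3 lower hair shaft genes 1 without C2, K1 or K3.

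Single markers of endothelium and of erythroid cells rose. Of 13 endothelial genes the VEGF receptor gene Flt1 rose (2.14 ± 1.54 to 14.2 ± 9.90 CPM), under both adjustments, and the list did not pass (camera adjusted p = 0.849), with a median log2 fold change of -0.02 (0.02 with library size alone), a mean of 0.09 and a downward test. Of 2 tested erythroid genes Epor, the erythropoietin receptor gene, rose by 2.43 ± 0.38 (SE). edgeR called 0 of 8 melanocyte genes (4 higher at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom), 0 of 15 Langerhans and myeloid genes (2 lower at that p, 2 by DESeq2, 0 by limma-voom), and 0 of 7 muscle, 6 Schwann cell and 2 T cell genes (0 at that p, 0 by DESeq2 and 0 by limma-voom). The members with the highest means were Ednrb (-0.59) for melanocytes, Cd74 (-0.40) for myeloid cells, Tnni2 (-0.89) for muscle, Erbb3 (0.18) for Schwann cells and Itgae (0.04) for T cells, in log2 fold change. Of these lists, none that was tested passed (camera adjusted p = 0.131 for melanocytes, 0.111 for Langerhans and myeloid cells, 0.208 for muscle and 0.775 for Schwann cells). The Langerhans and myeloid list passed downward (camera adjusted p) without C1 (0.0459), C2 (0.00902) or K3 (0.00942), and 1 melanocyte gene was called higher without C1. Of the sort markers, named after their values were seen, Epcam had 168, 131 and 116 CPM in C1, C2 and C3 and 381, 216 and 207 CPM in K1, K2 and K3, and did not pass (edgeR adjusted p = 0.0598). Itga6, the gene of α6-integrin, had 857, 1412 and 1457 CPM in C1, C2 and C3 and 1092, 1020.5 and 1149 CPM in K1, K2 and K3, and Ly6a, the gene of Sca1, had 15.1 CPM in C1 and 48.8 to 63.5 CPM in the other libraries. Mitochondrially encoded genes, 15 listed, were not in the files. Calls were lost (edgeR adjusted p) for Flt1 without C1, C2, K1 or K2 (0.0679 to 0.120), with replicates 2 and 3 alone (0.0990) and by limma-voom (0.0601).

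**Figure D3:**
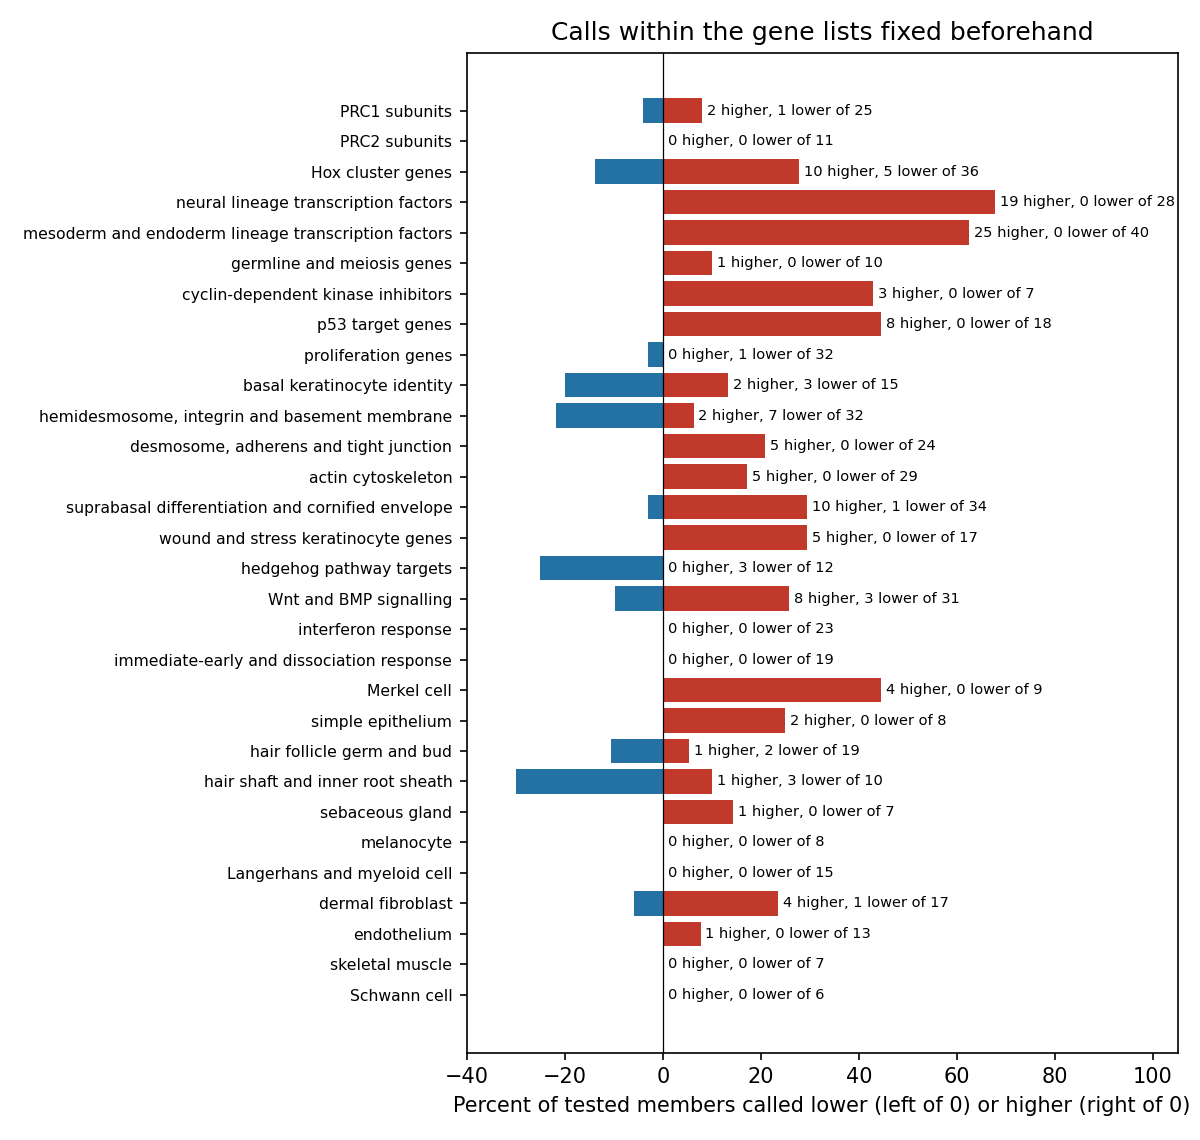
Percentage of the tested members of each list called lower (left, blue) and higher (right, red) in the knockout-labelled libraries. The neural (19 of 28) and the mesoderm and endoderm (25 of 40) transcription factors had the largest shares of higher genes among the longer lists.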

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

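The settings with the Xist covariate, with replicates 1 and 2 or 2 and 3 alone, with the second component term, with the 20 most counted genes removed and with the GC and length offset were chosen after the data were seen. Every gene called in the comparison kept its direction in every setting that tested it, which was likely since all settings used the same libraries. Among the rest, Ring1, which was not called, turned from -1.29 to 0.08 in log2 fold change with the Xist covariate, and the offset turned the excess of higher genes to 903 higher against 930 lower. Over all settings, 2302 values of the 131 named genes kept their side of the threshold, 20 passed it newly and 163 no longer passed, and of the list tests 500 kept it, 34 passed newly and 33 no longer passed. Leaving out 1 library gave 811 to 1393 genes changed, 630 to 957 higher, 174 to 436 lower and 13 to 16 lists, with fewer samples. The Xist covariate, which takes a degree of freedom, gave 550 changed, 480 higher and 70 lower, and 31 named genes no longer passed. Replicates 1 and 2 alone gave 439 changed, 354 higher and 85 lower, with 38 named genes no longer passing, and replicates 2 and 3 alone 2694 changed, 1633 higher and 1061 lower, with 4 libraries in each setting, and the cause of the difference was not tested. A term for the second component, on which both replicate 1 libraries stand apart, gave 814 lower genes (2251 changed), and the cause was not tested. DESeq2 called 2535 changed, 1639 higher and 896 lower, a set that holds all 1512, and the cause of the larger number was not tested. The GC and length offset called 1833 changed, and the cause was not tested beyond the GC test given in the next part. With an estimated correlation between genes 2 lists passed in place of 13, and with fry 11, and the cause was not tested.

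The other settings stayed within 1.5 times. Changed genes were 1513 with DESeq2 size factors, 1487 with library size alone, 1573 with limma-voom, 1321 with a 2-fold minimum, 1518 with 20 genes removed, 1737 without a filter (19884 tested) and 1371 with the strict filter (12626 tested).

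The replicate numbers are shared by both groups and the labels do not say that they pair libraries, so the numbers were not taken as pairs. The deviations of same-numbered libraries from their group means correlated at 0.175, 0.228 and 0.0773. All 6 libraries correlated best with their own number among the other group's, a weak hint of pairing from the data and not the design. These 6 results are not independent, since the deviations were taken from the mean of each group's 3 libraries. With a replicate block 1451 genes changed, 1016 higher and 435 lower, and 13 lists passed.

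Depth limits what a count of 0 can exclude, 0.0962 to 0.158 CPM in a single library.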

Other observations

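The lists and families in this part were written after the results were seen, and of the tests of explanations those of the splits, of composition scaling, of GC content on the count of higher genes and of Hox position were also written after, so their p-values describe what was seen and test nothing independent of it. Imprinted genes, which are expressed from 1 parental copy and include many growth regulators, were in part higher in the knockout-labelled libraries. Of 46 tested imprinted genes 17 rose, 1 fell and 28 did not pass (camera adjusted p = 4.35e-05; adjusted p = 0.0415 with an estimated correlation, both over the 4 lists added). All 6 tested genes of the Dlk1-Dio3 cluster on chromosome 12 rose by edgeR, 5 with DESeq2 size factors, library size alone or the GC and length offset, and 4 by limma-voom. The maternally expressed noncoding RNA Meg3 rose from 12.9 ± 0.992 to 275 ± 132 CPM and Rian by 4.49 ± 0.30 on the log2 scale (SE), and these calls held without any 1 library. Mirg (4.77), Rtl1 (4.18), Dio3 (4.57) and Dlk1 (2.13) completed the cluster, and reads of Rtl1 and of its antisense transcript cannot be told apart. Elsewhere Zdbf2 (3.80), Peg10 (2.39) and Cdkn1c rose, the trophoblast factor Ascl2 fell (-2.22), and the growth factor gene Igf2 (0.07) and its neighbour H19 (-0.70) did not pass, although H19 was lower in every knockout-labelled library than in any control-labelled one (edgeR adjusted p = 0.107). With the GC and length offset 14 imprinted genes rose and 3 fell. Calls were lost (edgeR adjusted p) for Mirg without C3, K1, K2 or K3 (0.0508 to 0.0920), Dlk1 without C2, C3, K1, K2 or K3 (0.0791 to 0.147), Dio3 without C1, C2, C3, K2 or K3 (0.0824 to 0.171), Rtl1 without C2 or C3 (0.0575 to 0.0599) and Ascl2 without K2 or K3 (0.0527 to 0.0566). The 17 higher imprinted genes became 11 without C2, 6 without C3, 7 without K2 and 10 without K3, and the 6 of the cluster 3 without C2, K2 or K3, 2 without C3 and 4 without K1.

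Abundant transcripts of neurons followed the neural transcription factors in part. Of 13 tested (20 listed) 7 rose (camera adjusted p = 1.18e-08, and 0.0171 with an estimated correlation). Here too a transcript silent in the control-labelled libraries was tested only if it was counted in the knockout-labelled ones. Among those that rose were the neurofilament gene Nefh (ratio 111, 37.6 to 540.4, from 3 counts), Ina (5.54), Tubb3 (5.26) and Map1b (2.73 ± 0.40, SE). Snap25, a synaptic protein gene, had 0.621 and 0.620 CPM. All 4 nuclear factor I genes, which bind enhancers of epithelial stem cells, fell, with log2 fold changes of -1.69 ± 0.23 for Nfia, -1.04 ± 0.21 for Nfib and -1.02 ± 0.17 for Nfix (SE). Among 245 families of genes with a shared name stem, 6 of 9 Cacna genes, which encode voltage-gated calcium channels, rose (Fisher adjusted p = 0.00458 over 490 tests), with Cacna1c at 3.67 ± 0.26 and Cacna2d1 at 5.52 ± 0.52 (SE). Of the collagens 7 of 36 fell (Fisher adjusted p = 0.0188) and 4 rose. The family median turned from -0.02 to 0.04 when the 20 most counted genes were removed, and was -0.52 with the GC and length offset. Col4a5, Col4a6 and Col12a1 (-1.38, -1.15 and -1.14) were lower while Col2a1, the collagen of cartilage, was higher (8.06). Calls were lost (edgeR adjusted p) for Nfib without K2 or K3 (0.0636 to 0.0750), the 6 Cacna genes became 4 without C1, C3 or K2, and the 7 lower collagens 4 without K2.

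More genes were higher than lower, with a lowest share of 70.8% over 3 other scalings, but these moved the median log2 fold change of all genes so little that they cannot test scaling. The higher genes had a median GC content of 52.9% against 47.3% for the lower. With an offset for GC content and length the share that was higher fell to 49.3%. The offset was fitted to each library's deviation from the mean of all libraries, whatever the label. It therefore also removes any real difference between the groups that goes with GC content or length. A trend of that kind can account for the count of higher genes over lower, but whether it is technical cannot be told. The trend as fitted did not account for the large changes, since 79.2% of calls of 4-fold or more were still higher with the offset. These were 582 against 153, and 86.3% were higher without it. The offset moved the median log2 fold change of all tested genes by only -0.13. It could thus hardly have turned changes of 4-fold, so this was a weak test. With the Xist covariate the higher genes had a median log2 fold change of 2.46 against 2.60 without it, all 1068 with the same sign. These genes were chosen by their calls in the same libraries, so they were likely to keep their changes. K1 and K2 also differed from C1 and C2 in Xist, so sex and label go together in those libraries. The sex make-up of the libraries is therefore not excluded. The genotype that the labels give is the biological explanation in the design, and no test here decides on it.

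The Ring1 counts of both replicate 3 libraries went against their labels. An exchange of C3 and K3 was excluded, since 99.7% of the genes called higher from replicates 1 and 2 alone (353 of 354) were higher in K3 than in C3. Cells that kept Ring1 may be part of K3, but the genes called higher without K3 had a median log2 ratio of K3 to the other 2 knockout-labelled libraries of -0.28 with an SD of 0.60, and the same ratio was -0.20 for K2, so this test cannot tell. Low Ring1 and both Xist and Ddx3y in C3 are given as measured, with no biological explanation tested.

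The change of a Hox gene went with its paralog number. Paralog number and log2 fold change had a Spearman correlation of 0.73 over 36 genes (permutation p = 1e-05, the smallest possible with 100000 permutations). It was 0.72 to 0.76 with 1 library left out, so position fits, though not apart from the control-labelled level given below. The permutation treated the genes as independent, while neighbours in a cluster may share reads and change together. Its p is therefore likely too small. A trend in GC content and length was excluded, since the correlation was 0.75 with the offset. The order along the cluster, rather than the number in the name, was not tested apart. Nor was the level in the control-labelled libraries, which differed between lower and higher genes. The lower genes had means of 18.6 to 42.8 CPM there, and the higher genes 0 to 1.82 CPM apart from Hoxb9 (7.46 CPM). A gene barely counted there can hardly fall. Hoxd3 and Hoxd4, at 0.627 and 0.860 CPM there, did not rise (log2 fold changes -0.12 and -0.54, neither passed).

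A hypothesis was that higher genes lie side by side on chromosomes, as genes of shared Polycomb domains would. Of 14556 tested genes in chromosome order, 139 adjacent pairs were both higher, against a mean of 75.9 and a maximum of 113 in 100000 shuffles (one-sided permutation p = 1e-05, the smallest possible), so position fits. Shuffling within classes of GC content and level gave a mean of 82.4 and a maximum of 110, and leaving out 1 library 38 to 109 pairs against 25.9 to 60.0 in shuffles. The neighbours Dmrt1, Dmrt2 and Dmrt3 on chromosome 19, all without control-labelled counts, were at least 151-fold, 121-fold and 314-fold higher. Duplicated genes and overlapping transcripts can also lie side by side, and were not taken out.

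The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The split by label called 1512 genes and the highest other split 1, so that 1 of 10 splits reached the count by label.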
